A study of Macaca mulatta with 8 samples.

How the data were processed

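Nuclear RNA was measured by droplet single-nucleus sequencing in 8 libraries, 1 from ACC and 1 from LPFC of each of 4 male rhesus monkeys aged 8.5 to 24.8 years. The labels give the regions only by these abbreviations. Per the labels, frozen tissue was homogenised, nuclei were sorted by flow cytometry on scatter and DAPI fluorescence, and libraries were made on the 10x Genomics Chromium platform and sequenced on an Illumina instrument. The deposited matrices hold UMI counts per gene and nucleus barcode, unnormalised, for the barcodes the authors called as nuclei with Cell Ranger. A UMI is a tag that marks 1 captured RNA molecule. Per the file headers these counts came from Cell Ranger 6.0.1 for batch 1 (AM365 and AM367) and 7.0.0 for batch 2 (AM368 and AM372), so version and batch coincide. Each batch held both regions and 1 animal of each age group. The genome build, the annotation release and whether intronic reads were counted are not given in the sources used here. The matrices listed 24037 genes, of which 8457 had no symbol. Symbols for 871 of these came from the gene table, and 8119 genes stayed under their identifier. 515 symbols differ between files and table, and these genes are among those named by their identifier. Genomic positions were not used here.

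Nuclei with at least 500 UMIs, at least 300 genes and at most 5% mitochondrially encoded UMIs were kept. Scrublet, as in scanpy 1.11.5, scored doublets in each library, and the highest-scoring 0.8% per 1000 nuclei were removed. This left between 1781 and 2567 nuclei per library, with total depths of 5623234 to 18184084 UMIs per library before filtering. Counts were log-normalised, and 3000 variable genes ranked within libraries were scaled within library. The muscarinic, nicotinic and acetylcholine handling lists and mitochondrially encoded genes were kept out of these. Clusters were found from 30 principal components and 15 neighbours with leidenalg 0.10.2 at resolution 1, and neurons were clustered again by class. Clusters were named by marker genes and not by scores. Clusters 32, 33, 34, 35 and 44 carried markers of a pair of classes each and were left out, as were subclusters E16, E18, I16 and I22, led by genes of another class. Excitatory subcluster E6 (319 nuclei, median 813 UMIs) stayed in its class without a subclass name, as did other subclusters whose markers named no single subclass. Software was Python 3.11.15 with anndata 0.12.19, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3.

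Counts were summed per library (region) or per animal (receptor classes, neuron classes, age) over the nuclei of a class, with at least 20 nuclei per sum. The sums were compared with the quasi-likelihood test of edgeR 4.0.16 after TMM scaling and filterByExpr, with a Benjamini-Hochberg adjusted p under 0.05 as threshold. Region was fitted with batch as covariate. Sums of 1 animal always entered as a pair in the receptor and neuron class comparisons, and age was fitted with batch, 2 older animals against 2 younger. CHRM1-only nuclei had at least 1 CHRM1 UMI and no CHRM2 UMI, and CHRM2-only nuclei the reverse. Both genes were left out of that test. CHRM2-positive nuclei were compared with CHRM2-negative nuclei matched on total UMIs within library. The deposited labels name the animal of each library, which makes region a paired comparison, and the pairing was checked on the counts. Over 24 pairs of class and animal, the ACC and LPFC sums of 1 animal correlated at 0.132 to 0.774 (across genes, which are not independent replicates) and matched the same animal best in 24 of 24. Region was therefore also fitted with the animal as block in place of batch, and both values are given. No 2 libraries were copies, with a lowest chi-square per gene of 5.93 between any pair.

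Gene lists, 24 in number, were tested with camera of limma 3.58.1 at the preset correlation of 0.01, and again with an estimated correlation and with fry. Named genes followed a rule: CHRM1 to CHRM5, the 8 highest and 8 lowest log2 fold changes that passed, moved the same way in every animal and reached 10 CPM in the higher group, and up to 12 list members with the lowest adjusted p. Some genes that met the rule are not reported here, nor entered in the search for outlying values. CPM are UMI counts scaled to a common total per sum. In the comparisons that total is the one after filtering and TMM scaling. Means and SDs of a gene there can therefore differ from those given per class or subcluster. A list count over all genes stands beside the count adjusted over the list alone. Groups, comparisons, lists, the naming rule and 174 alternatives were set before the data were examined. The comparison of CHRM1-positive with CHRM1-negative nuclei was added later. Shares of nuclei and shares with a receptor UMI were compared by exact permutation tests, two-sided, whose smallest possible p is 0.0286 for 4 against 4 libraries. These tests did not use the pairing of libraries by animal, so differences between animals add to their spread. Receptor shares were taken after thinning each nucleus to 1000 UMIs, with shallower nuclei left out. Co-detection was measured as the Mantel-Haenszel odds ratio over strata of library and depth decile per animal, with an exact two-sided sign-flip test over 4 animals, whose smallest possible p is 0.13. Shares of 0 carry the upper limit that 3 counts would give, for counting error only.

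The tests were tested on counts simulated from the pooled gene means, depths and dispersions of these sums, with known genes changed. No differences between animals or batches were simulated, so the recoveries below leave these out. In excitatory neurons the region fit recovered 5.97% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 87.9% of those changed 4-fold, and the fit with the animal block 55.2%, 82.1% and 100%. In microglia the region fit recovered 31.3% at 2-fold and 90.9% at 4-fold. The comparison of CHRM1-only with CHRM2-only excitatory neurons recovered 44.8% at 1.5-fold and 80.6% at 2-fold, and its inhibitory counterpart 35.8% and 76.1%. The age fits recovered 34.3% at 2-fold in excitatory neurons and 2.99% in oligodendrocytes. Unchanged genes were called too, 7 of 105 calls in the excitatory region fit, 14 of 172 with the block and 8 of 93 in microglia. In CHRM1-only against CHRM2-only neurons they were 17 of 167 in excitatory and 4 of 144 in inhibitory neurons. In the age fits they were 6 of 86 in excitatory neurons and 0 of 35 in oligodendrocytes. Alternatives included DESeq2 1.42.0, RLE size factors, no low-count filter, no batch covariate, each batch and region alone, each library or animal left out, at least 1000 UMIs per nucleus, doublets kept, and nuclei matched on subcluster.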

Results

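RNA from single nuclei was counted in 8 libraries, 4 from ACC and 4 from LPFC, each animal giving 1 of each. AM367 (8.5 years) and AM368 (8.9 years) were the younger animals, and AM372 (20.8 years) and AM365 (24.8 years) the older ones. For AM367, the ACC library held 8029736 UMIs and gave 1917 nuclei with a median of 3137 UMIs, and the LPFC library held 7581987 UMIs and gave 2543 nuclei with a median of 2233. For AM365, the ACC library held 5623234 UMIs and gave 1815 nuclei with a median of 1903 UMIs, and the LPFC library held 7099136 UMIs and gave 2567 nuclei with a median of 1811. For AM368, the ACC library held 13124862 UMIs and gave 2002 nuclei with a median of 3834 UMIs, and the LPFC library held 13008779 UMIs and gave 2128 nuclei with a median of 4606. For AM372, the ACC library held 14561070 UMIs and gave 2274 nuclei with a median of 3986 UMIs, and the LPFC library held 18184084 UMIs and gave 1781 nuclei with a median of 7449.

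Markers named excitatory neurons (5821 nuclei), inhibitory neurons (3640), oligodendrocytes (4380), oligodendrocyte precursors (849), astrocytes (1198), microglia (914) and a few vascular cells. To ask whether the regions differ in make-up, the share of each class was compared between 4 ACC and 4 LPFC libraries. Excitatory neurons made up 31.6% ± 7.79 (SD, n = 4) of nuclei in ACC and 36.5% ± 2.33 in LPFC, and were higher in ACC in 1 of 4 animals (exact permutation test, p = 0.314, adjusted 0.55). Inhibitory neurons made up 22.5% ± 4.44 and 20.3% ± 2.11 (exact p = 0.486, adjusted 0.68). Microglia made up 6.32% ± 1.06 in ACC and 4.49% ± 0.79 in LPFC, higher in ACC in 4 of 4 animals by 1.71 percentage points in batch 1 and 1.94 in batch 2 (exact p = 0.0571, adjusted 0.4). Oligodendrocyte precursors were also higher in ACC in 4 of 4 animals, at 5.65% ± 1.32 against 4.34% ± 0.965 (exact p = 0.171, adjusted 0.55). Oligodendrocytes made up 26.0% ± 13.7 and 26.0% ± 7.76, and astrocytes 6.72% ± 3.85 and 7.01% ± 4.43. None of the 7 class shares passed the threshold by this test, 0 of them at an unadjusted exact p under 0.05. The test left out the pairing by animal, and at its smallest possible p of 0.0286 a single class could not pass after adjustment. It therefore does not rule out a difference. Within batches the excitatory difference was -1.69 percentage points in batch 1 and -8.08 in batch 2, and the inhibitory difference 1.79 and 2.69.

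The first question was which cell classes carry muscarinic receptor transcripts. CHRM3, which encodes a receptor coupled to Gq, had the most UMIs in both neuron classes. Its level was 1224 ± 108 CPM (SD, n = 4 animals) in excitatory and 1204 ± 133 CPM in inhibitory neurons. CHRM2, whose product couples to Gi, stood at 73.3 ± 9.92 and 91.6 ± 9.90 CPM, and CHRM1, coupled to Gq, at 20.5 ± 4.79 and 22.8 ± 9.16 CPM. Counts of different genes also depend on intron counting and on the annotation, which are not known here. These CPM therefore do not give the ratio between receptor RNAs. After thinning to 1000 UMIs, 61.9% of excitatory neurons had a CHRM3 UMI, 5.51% a CHRM2 UMI and 1.90% a CHRM1 UMI, and 56.5%, 6.75% and 2.25% of inhibitory neurons. Microglia, taken as background, had 3.79%, 0.206% and 0.511%, with a median depth of 1169.5 UMIs against 6457 in excitatory and 4229 in inhibitory neurons. Without thinning the excitatory shares were 89.3%, 18.2% and 14.6%, the inhibitory shares 76.1%, 16.5% and 11.3% and the microglial shares 5.68%, 0.89% and 0.78%. Oligodendrocytes had 125 ± 30.7 CPM of CHRM3 and a UMI in 8.78% of thinned nuclei. CHRM4 gave 75 UMIs in excitatory and 19 in inhibitory neurons, and CHRM5 gave 4 and 1, so CHRM5 was barely detectable at this depth. In microglia, CHRM4 and CHRM5 were seen in 0 of 574 thinned nuclei, which allows a share with a UMI of up to 0.523%.

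Excitatory and inhibitory neurons were next compared over the cholinergic genes. Inhibitory neurons had more CHRNA7, the nicotinic alpha subunit of fast calcium-permeable receptors (112 ± 6.16 against 39.7 ± 11.1 CPM; log2 fold change -1.51 ± 0.14, adjusted p = 1.18e-05), and more CHRNA2, another nicotinic subunit (7.79 against 0.255 CPM; log2 fold change -4.94 ± 0.40, adjusted p = 4.51e-06). BCHE, which encodes a cholinesterase, was also higher in inhibitory neurons (log2 fold change -3.77 ± 0.39, adjusted p = 3.01e-05). CHRM2 was slightly higher there, at 91.0 ± 2.76 against 74.5 ± 15.9 CPM (log2 fold change -0.29 ± 0.10, adjusted p = 0.0389), whereas CHRM1 (adjusted p = 0.532) and CHRM3 (adjusted p = 0.742) did not pass. Of 14 measured cholinergic genes 6 passed, all higher in inhibitory neurons. The others were CHRNA6 (-0.94) and RIC3 (-0.19), a chaperone of nicotinic receptors. By DESeq2 3 of them passed. ACHE, CHRM4, CHRNA3, CHRNA5, CHRNB2 and PRIMA1 did not pass. Over all genes 6879 of 14757 passed in this fit, so passing alone does not single out the cholinergic genes. Other lists also held genes that passed. The 13 measured interneuron peptides and calcium-binding proteins were all lower in excitatory neurons (13 adjusted over the list alone; median -3.82; camera adjusted p = 2.04e-16, and adjusted p = 0.152 with an estimated correlation). Of 17 ionotropic glutamate receptor genes 5 were higher and 10 lower in excitatory neurons (5 and 10 adjusted over the list alone; camera adjusted p = 0.000578, and adjusted p = 0.350 with an estimated correlation). All 7 measured immediate early genes were higher (7 adjusted over the list alone; camera adjusted p = 0.0264, and adjusted p = 0.380 with an estimated correlation).

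CHRM2 transcripts were concentrated in a few neuronal subclusters, while CHRM1 transcripts were spread more evenly. Among 17 excitatory subclusters, CHRM2 ranged from 1.78 CPM in upper-layer subcluster E15 to 792 ± 175 CPM in E11 (237 nuclei). E11 had raised markers of 2 deep-layer lists and so got no single name. These lists were extratelencephalic or near-projecting (7 raised) and corticothalamic or layer 6b (5 raised). Leading genes of E11 included HTR2C, PCP4 and QRFPR. The deep intratelencephalic subcluster E17 had 234 ± 55.7 CPM, E9 199 ± 43.6 CPM and middle-layer E4 181 ± 66.9 CPM, against 6.52 ± 3.23 CPM in the largest upper-layer subcluster, E1. E11 also had the least CHRM3, 30.2 ± 8.15 CPM, where E1 had 1473 ± 94.5 CPM and E12, deep corticothalamic or layer 6b, 1774 ± 311 CPM. CHRM1 stayed between 9.69 CPM in E11 and 35.2 CPM in E12. The coefficient of variation over excitatory subclusters was 0.305 for CHRM1, 1.72 for CHRM2 and 0.404 for CHRM3.

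Inhibitory subclusters showed the same contrast. CHRM2 was highest in I21, an SST subcluster of 38 nuclei, at 986 ± 189 CPM, followed by PVALB subcluster I1 (204 ± 31.3 CPM), SST subclusters I4 (183 ± 80.5 CPM), I12 (182 ± 115 CPM) and I18 (154 ± 50.5 CPM), and VIP subcluster I3 (123 ± 26.7 CPM). A second PVALB subcluster, I2, had 25.1 CPM. CHRM3 was low in both PVALB subclusters, at 198 ± 44.2 CPM in I1 and 243 ± 29.0 CPM in I2, and lowest in LAMP5 or RELN subcluster I14 (16.4 ± 9.73 CPM), against 2665 ± 491 CPM in I12 and 2021 ± 271 CPM in I4. The coefficient of variation over 20 inhibitory subclusters was 0.514 for CHRM1, 1.95 for CHRM2 and 0.58 for CHRM3.

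**Figure D1:**
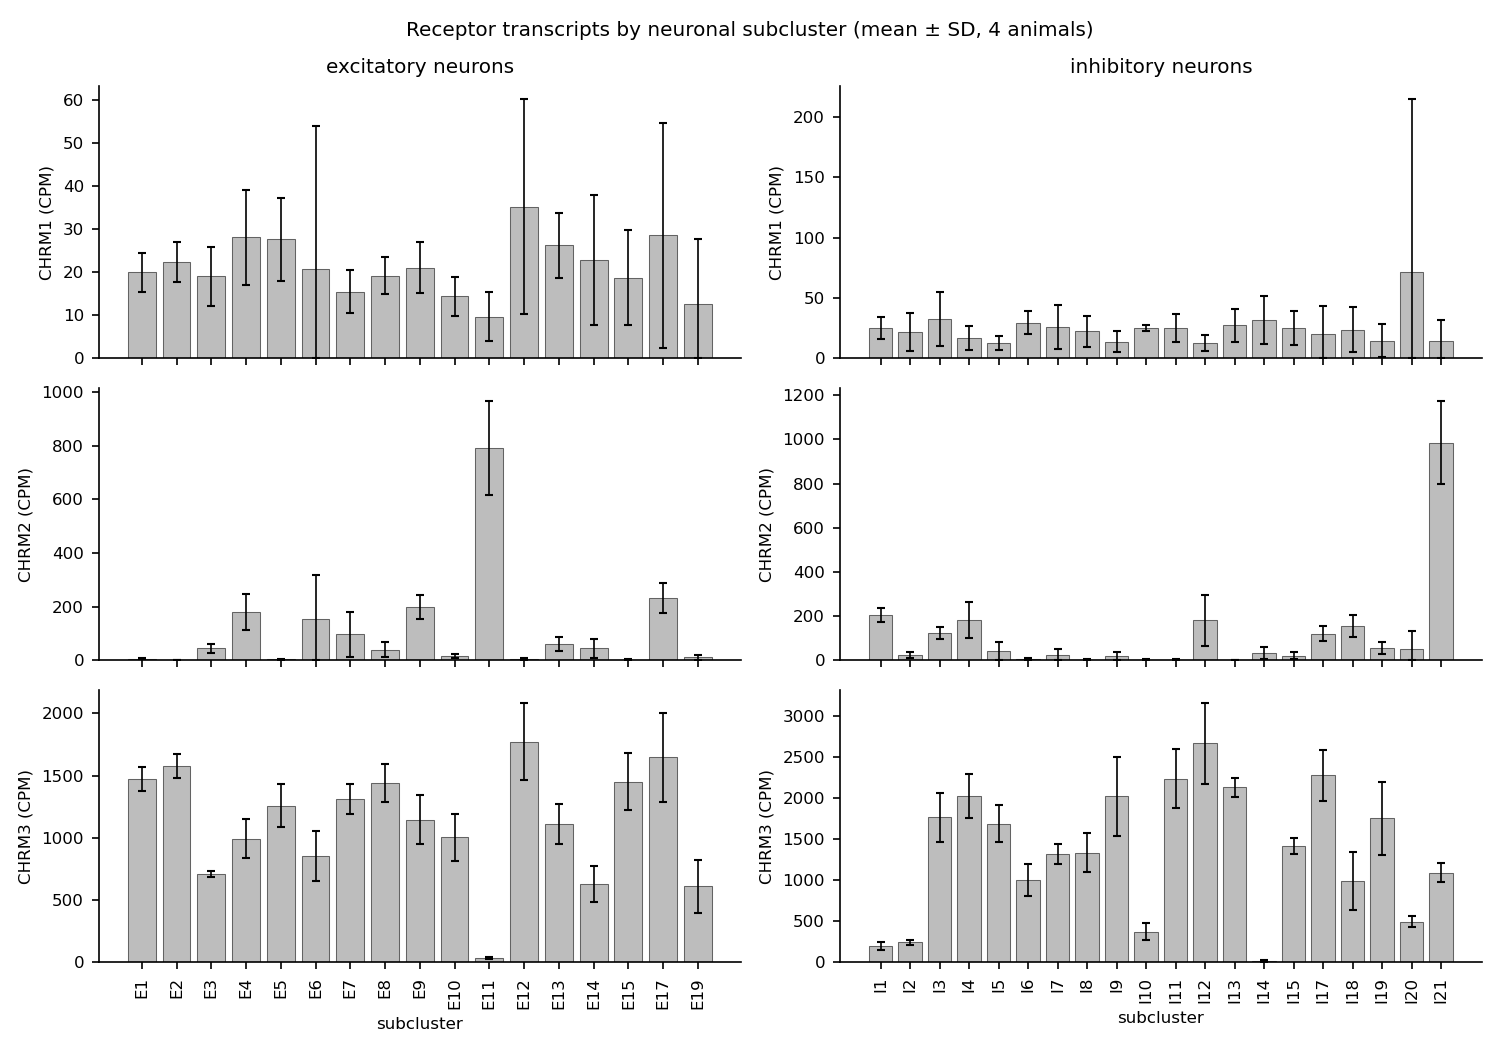
CHRM1, CHRM2 and CHRM3 in CPM (y axes) for each excitatory and inhibitory subcluster (x axes), with bars for the mean and lines for the SD of 4 animals. CHRM2 peaks in E11 at 792 CPM and in I21 at 986 CPM.

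Whether the regions differ in receptor-positive neurons was asked on nuclei thinned to 1000 UMIs. CHRM2 was seen in 5.93% ± 0.989 (SD, n = 4) of excitatory neurons in ACC and 5.08% ± 1.06 in LPFC (exact permutation test, p = 0.286), CHRM3 in 59.1% ± 5.92 and 64.7% ± 4.12 (exact p = 0.229), and CHRM1 in 1.90% ± 0.746 and 1.90% ± 0.774 (exact p = 1). In inhibitory neurons the shares were 6.72% ± 1.48 and 6.77% ± 1.14 for CHRM2 (exact p = 0.943), 55.0% ± 6.39 and 57.9% ± 2.64 for CHRM3 (exact p = 0.429), and 2.15% ± 1.47 and 2.35% ± 1.03 for CHRM1 (exact p = 0.83). The adjusted p was 1 for each of the 5 receptor genes in both classes, and a single gene could not pass after adjustment at the smallest possible p of 0.0286. In batch 1 and batch 2 the excitatory ACC minus LPFC difference was -0.044 and 1.74 percentage points for CHRM2, -4.30 and -6.83 for CHRM3, and -0.0782 and 0.0866 for CHRM1. The inhibitory differences were -0.786 and 0.689 for CHRM2, -0.853 and -5.03 for CHRM3 and 1.12 and -1.53 for CHRM1. Thinning left out 121 ACC and 88 LPFC excitatory neurons, and 22 and 26 inhibitory neurons. Unthinned excitatory shares were 18.8% ± 4.31 and 17.5% ± 3.50 for CHRM2, 88.3% ± 4.18 and 90.3% ± 1.01 for CHRM3 and 14.4% ± 3.29 and 14.7% ± 5.07 for CHRM1, with median depths of 7191 and 5694 UMIs. Thinned microglia had 0.206%, 3.79% and 0.511% at a median of 1169.5 UMIs.

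**Figure D2:**
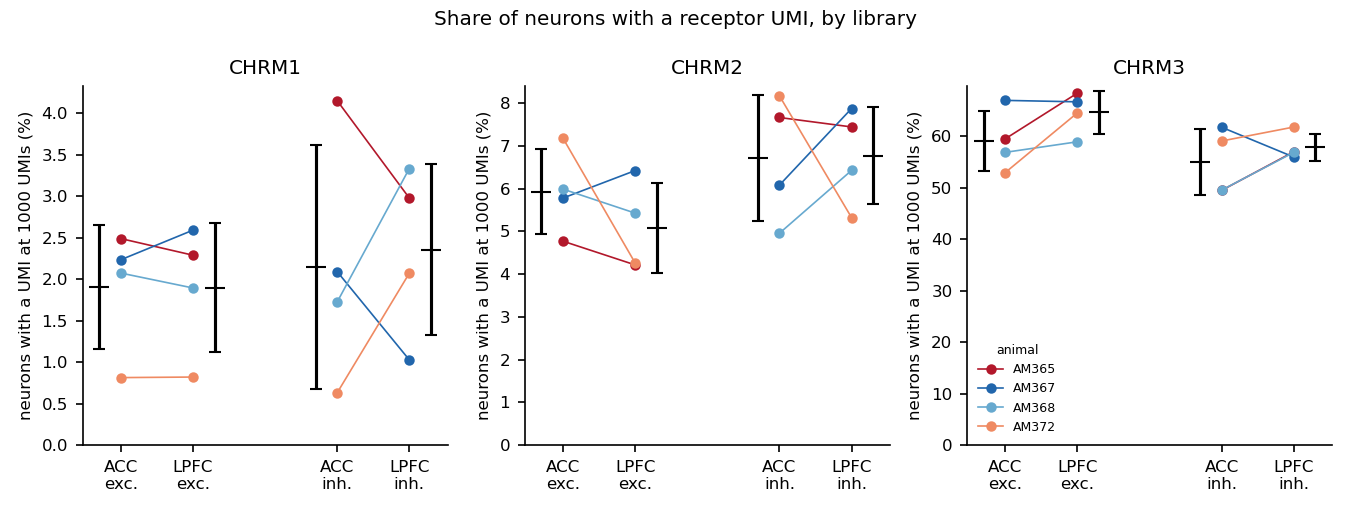
Percent of neurons with a CHRM1, CHRM2 or CHRM3 UMI after thinning to 1000 UMIs (y axes) in ACC and LPFC, for excitatory (exc.) and inhibitory (inh.) neurons; joined points are 1 animal and black marks the mean ± SD of 4 animals. CHRM3 in excitatory neurons averaged 59.1% in ACC and 64.7% in LPFC.

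Co-detection showed how the receptors combine in single nuclei. Excitatory neurons with CHRM2 had CHRM3 less often than depth alone gave, though 829 nuclei had both, with an odds ratio of 0.119 (range over 4 animals 0.0591 to 0.167, below 1 in 4 of 4; exact sign-flip test, p = 0.13, the smallest possible). CHRM1 and CHRM3 were found together more often than depth alone gave, with an odds ratio of 1.87 (1.40 to 2.48; exact p = 0.13). CHRM1 and CHRM2 were paired at an odds ratio of 1.02 in excitatory neurons (0.751 to 1.20, 175 nuclei with both; exact p = 0.875) and 0.92 in inhibitory neurons (0.519 to 1.33; exact p = 0.875). In inhibitory neurons CHRM2 with CHRM3 gave 1.33 (0.945 to 1.53; exact p = 0.25; 0.954 in ACC and 2.13 in LPFC) and CHRM1 with CHRM3 gave 0.771 (0.576 to 1.18; exact p = 0.25). With subcluster added to the strata, CHRM1 with CHRM3 gave 1.85 in excitatory neurons (0.744 to 5.05, below 1 in 2 of 4 animals; exact p = 0.5). There CHRM2 with CHRM3 moved to 0.729 in excitatory neurons (0.535 to 0.959) and to 2.23 in inhibitory neurons (1.86 to 2.78). These ratios count nuclei with a UMI and miss transcripts that were not captured.

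To ask what sets neurons with CHRM1 apart from neurons with CHRM2, 644 CHRM1-only and 880 CHRM2-only excitatory nuclei were summed per animal. CHRM1-only neurons had more of the upper-layer genes CBLN2, a secreted synapse organiser (177 against 70 CPM; log2 fold change 1.36 ± 0.12, adjusted p = 1.30e-06), and RASGRF2, a Ras activator (log2 fold change 1.05 ± 0.085, adjusted p = 8.93e-07). CHRM2-only neurons had more HTR2C, a serotonin receptor gene (232 ± 96.2 against 3.03 ± 2.49 CPM; log2 fold change -6.31 ± 0.19, adjusted p = 1.04e-11), and more PCP4, a calmodulin regulator (log2 fold change -3.86 ± 0.24, adjusted p = 7.22e-08). CHRM3 was higher in CHRM1-only neurons, at 1386 ± 212 against 911 ± 179 CPM (log2 fold change 0.62 ± 0.066, adjusted p = 1.44e-05). Of 12007 genes tested 1079 passed, 570 higher and 509 lower in CHRM1-only neurons, with 1004 moving the same way in all 4 animals and 313 over 2-fold. DESeq2 called 499. The highest log2 fold changes were those of ADAM18 (3.37), ACVR1C (3.21), FBN2 (2.85), FREM3 (2.84), PCDH8 (2.77), INPP5D (2.63), JAG1 (2.33) and CBLN4 (2.28). ACVR1C encodes an activin receptor and JAG1 a Notch ligand. After HTR2C and PCP4 the lowest were QRFPR (-3.83), PLPP3 (-3.62), SORCS2 (-3.29), ST8SIA2 (-3.22) and IL16 (-3.18), and SMYD1, with 3 UMIs in CHRM1-only and 83 in CHRM2-only sums, was near the detection floor. LRRTM4, a postsynaptic adhesion gene, was higher in CHRM1-only neurons (5018 ± 1162 against 1793 ± 315 CPM; log2 fold change 1.48 ± 0.073, adjusted p = 5.27e-09).

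Layer and signalling lists moved in the same comparison. All 7 middle-layer genes were lower in CHRM1-only neurons (7 adjusted over the list alone; median -1.04; camera adjusted p = 1.17e-10, and adjusted p = 0.122 with an estimated correlation). Of 14 measured deep-layer genes 2 were higher and 8 lower (2 and 10 adjusted over the list alone; camera adjusted p = 4.32e-17, and adjusted p = 0.0846 with an estimated correlation), ETV1 (-1.30) among the lower. Of 7 upper-layer genes 5 were higher and 1, PDZRN4 (-1.22), lower (5 and 1 adjusted over the list alone; camera adjusted p = 1.01e-05, and adjusted p = 0.180 with an estimated correlation). In the list of Gq signalling genes, which act downstream of CHRM1 and CHRM3, 7 of 21 were higher and 3 lower (10 and 3 adjusted over the list alone; camera adjusted p = 0.000509, and adjusted p = 0.205 with an estimated correlation). Postsynaptic scaffold and kinase genes were higher in 5 of 16 and lower in 0 (5 and 0 adjusted over the list alone; camera adjusted p = 8.77e-06, and adjusted p = 0.122 with an estimated correlation). Metabotropic glutamate receptors were lower in 3 of 7, GRM4 (-2.20) among them (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.00354, and adjusted p = 0.180 with an estimated correlation). The 9 measured monoamine receptors split into 3 higher and 3 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.00359, and adjusted p = 0.303 with an estimated correlation). The kainate receptor gene GRIK1 (-3.02), the cadherin CDH6 (-2.08) and the potassium channel gene KCNT2 (-1.08) were lower and KCNN2 (0.98) higher. The classes came from different subclusters. E11, E4 and E9 gave 22.4%, 19.3% and 14.7% of CHRM2-only nuclei, beside 4.07%, 7.39% and 4.78% of all excitatory neurons. E1 and E2 gave 25% and 16.6% of CHRM1-only nuclei, beside 19.4% and 14.3% of all excitatory neurons. These CHRM1-only shares lay nearer to all excitatory neurons than the CHRM2-only shares did. CHRM1-positive against CHRM1-negative excitatory neurons gave 12 genes, as described below. With nuclei matched on subcluster and library 19 genes passed, 14 of them shared with the 1079, and 189 of the 1079 changed direction, GRIK1 (0.063) and KCNT2 (0.0022) among them.

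The same comparison in inhibitory neurons used 321 CHRM1-only and 524 CHRM2-only nuclei. CHRM1-only neurons had more HTR1F, a serotonin receptor gene (148 ± 130.3 against 27.0 ± 16.8 CPM; log2 fold change 2.45 ± 0.18, adjusted p = 1.78e-11) and more of the glutamate receptor gene GRM8 (log2 fold change 1.43 ± 0.13, adjusted p = 2.21e-09). They also had more of the nicotinic subunit gene CHRNA2 (14.5 ± 4.58 against 2.31 ± 2.15 CPM; log2 fold change 3.07 ± 0.64, adjusted p = 0.00187). CHRM2-only neurons had more of the ion channel gene TRPM3 (371 against 95.3 CPM; log2 fold change -2.32 ± 0.20, adjusted p = 2.92e-10) and of POSTN (log2 fold change -2.02 ± 0.26, adjusted p = 1.73e-06), which encodes a matrix protein. CHRM3 did not pass (log2 fold change -0.12 ± 0.10, adjusted p = 0.728). Of 9249 genes 419 passed, 242 higher and 177 lower in CHRM1-only neurons, 360 of them the same way in all 4 animals. DESeq2 called 167. Other high log2 fold changes were those of COL21A1 (3.17), ADAMTS3 (3.11) and SMOC1 (3.08), and other low ones those of LRIG3 (-2.44), STK32A (-2.30), PPFIBP2 (-2.13) and TRDN (-1.79). SCGN had 39 UMIs in CHRM1-only and 2 in CHRM2-only sums. Nicotinic subunits were higher in 2 of 3 measured (2 adjusted over the list alone; camera adjusted p = 0.0425, and adjusted p = 0.453 with an estimated correlation). Potassium and HCN channel genes were higher in 4 and lower in 1 of 19 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0438, and adjusted p = 0.453 with an estimated correlation), with KCNT2 (1.66) up. Axon guidance and adhesion genes were higher in 7 and lower in 3 of 32 (7 and 5 adjusted over the list alone; camera adjusted p = 0.0425, and adjusted p = 0.503 with an estimated correlation), as with EPHA3 (2.04) and CDH20 (1.76). Monoamine receptors were higher in 1 of 6 (2 adjusted over the list alone; camera adjusted p = 0.0161, and adjusted p = 0.453 with an estimated correlation). I1 gave 27.3% of CHRM2-only and 14.0% of CHRM1-only nuclei, beside 12.5% of all inhibitory neurons. I4 gave 22.3% of CHRM2-only nuclei, beside 8.32% of all inhibitory neurons. Matched on subcluster and library, 14 genes passed, 10 of them shared with the 419, and 95 of the 419 changed direction, among them HTR1F (-0.097), CLSTN2 (-0.31), SV2C (-0.12) and UNC5C (-0.29). Without AM368 222 genes passed, and without AM372 273.

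**Figure D3:**
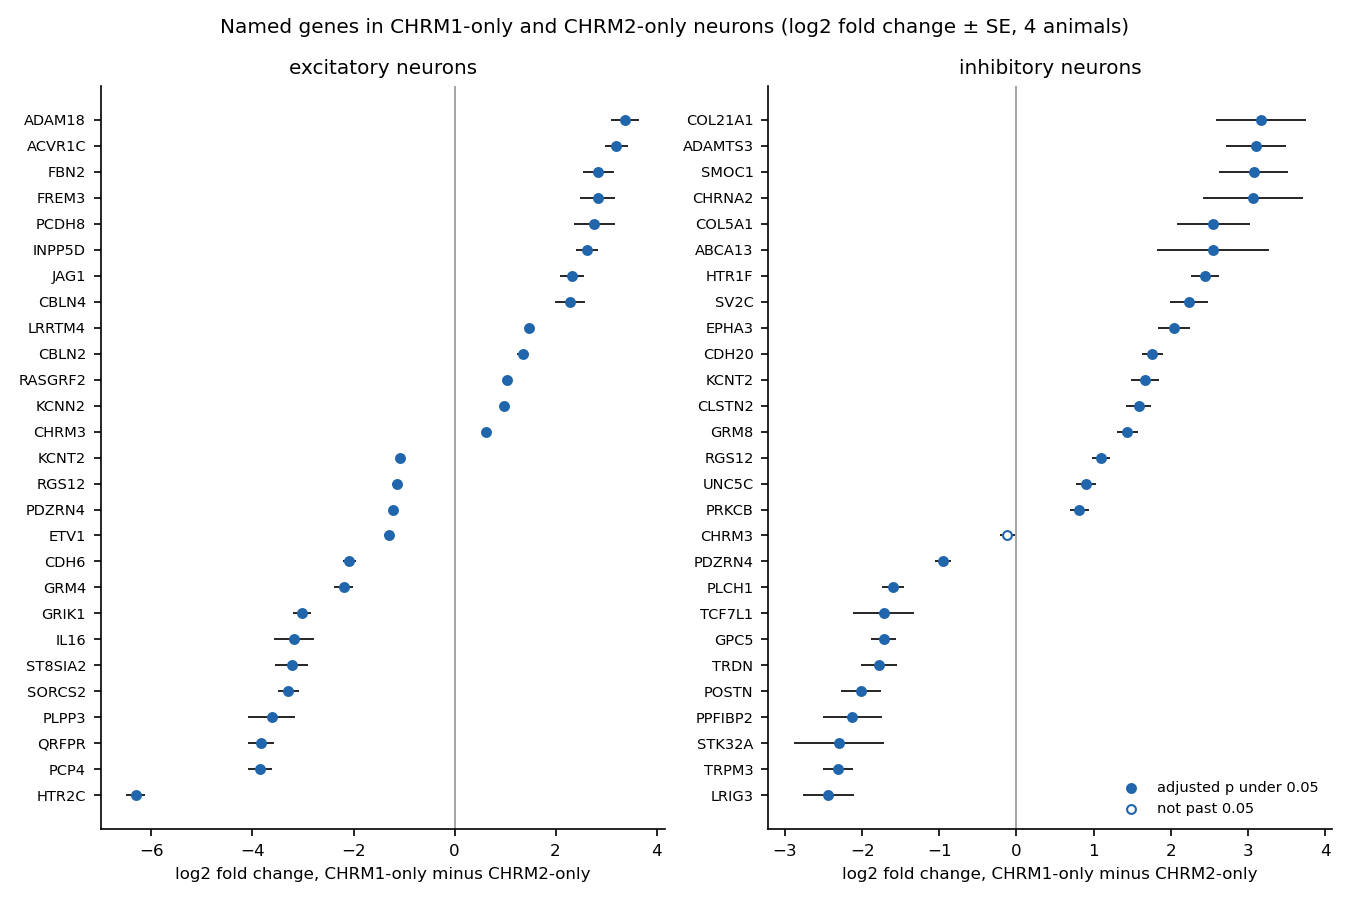
Log2 fold change, CHRM1-only minus CHRM2-only (x axes), of the named genes (y axes) in excitatory and inhibitory neurons; points are the fitted values of 4 animals, lines the SE, filled points passed an adjusted p of 0.05, and genes near the floor and a further gene are left out. HTR2C lies at -6.31 in excitatory neurons and HTR1F at 2.45 in inhibitory neurons.

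Whether that receptor class difference depends on region was tested with a class by region term. In excitatory neurons 47 of 9777 genes passed, among them PLCH1, a phospholipase gene (difference of log2 fold changes -1.26 ± 0.17, adjusted p = 9.46e-05), and DACH1, a transcription factor gene (difference of log2 fold changes 1.77 ± 0.23, adjusted p = 7.22e-05). CHRM3 did not pass (difference of log2 fold changes 0.18 ± 0.11, adjusted p = 0.805). Nuclei were not matched on subcluster for this term. PLCH1 is a leading gene of E4 and E9, which gave 19.3% and 14.7% of CHRM2-only nuclei. Unequal subcluster shares therefore stay open here. In inhibitory neurons edgeR called 0 of 7674 genes in 12 sums, where the excitatory fit had 16 since AM367 fell below 20 nuclei in 1 inhibitory sum, 374 had an unadjusted p under 0.05, and DESeq2 was not used here for this term. The smallest adjusted p was 0.127.

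CHRM2-positive neurons were then set against CHRM2-negative neurons matched on total UMIs, which asks what marks CHRM2 expression whatever the CHRM1 status. Most CHRM2-positive nuclei were the CHRM2-only nuclei above, so the answers are not independent. In excitatory neurons HTR2C (206 ± 92.8 against 3.90 ± 2.15 CPM; log2 fold change 5.83 ± 0.17, adjusted p = 5.85e-13), the ion channel gene TRPA1 (3.75), PCP4 (3.73) and GRIK1 (2.68) were higher in CHRM2-positive neurons, and ADAM18 (-3.32), ACVR1C (-3.14) and LRRTM4 (-1.35) lower. CHRM3 was lower, at 936 ± 186 against 1369.8 ± 187 CPM (log2 fold change -0.56 ± 0.053, adjusted p = 1.63e-06), and CHRM1 did not differ beyond its error (log2 fold change -0.043 ± 0.18, adjusted p = 0.940). Of 12585 genes 1295 passed, 627 higher and 668 lower, and DESeq2 called 594. With nuclei matched on cluster, library and total UMIs 25 passed, against 898 to 1015 in random draws of as many nuclei, and 268 of the 1295 changed direction. Without AM372 edgeR called 752. All 7 middle-layer genes were higher (7 adjusted over the list alone; camera adjusted p = 1.69e-11, and adjusted p = 0.0810 with an estimated correlation). Of 14 deep-layer genes 7 were higher and 2 lower (11 and 2 adjusted over the list alone; camera adjusted p = 1.08e-13, and adjusted p = 0.0797 with an estimated correlation). Gq signalling genes were higher in 2 and lower in 9 of 21 (3 and 12 adjusted over the list alone; camera adjusted p = 0.000167, and adjusted p = 0.0810 with an estimated correlation). Upper-layer genes were lower in 5 and higher in 1 of 7 (6 and 1 adjusted over the list alone; camera adjusted p = 2.77e-06, and adjusted p = 0.0810 with an estimated correlation). For the monoamine receptors the median was -0.15 while the mean of 0.62 and the test pointed up (camera adjusted p = 0.00334, and adjusted p = 0.175 with an estimated correlation).

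In inhibitory neurons CHRM2-positive nuclei had more TRPM3 (347 against 65.7 CPM; log2 fold change 2.35 ± 0.14, adjusted p = 5.73e-11), LDB2 (log2 fold change 2.03 ± 0.12, adjusted p = 4.18e-11), a transcriptional cofactor gene, and LYPD6 (log2 fold change 1.97 ± 0.34, adjusted p = 0.000495), whose product binds nicotinic receptors. They had less CHRNA2 (log2 fold change -2.75 ± 0.60, adjusted p = 0.00499), SMOC1 (-3.23), COL21A1 (-3.15) and HTR1F (-1.63). CHRM1 (log2 fold change -0.34 ± 0.22, adjusted p = 0.596) and CHRM3 (adjusted p = 0.883) did not pass. Of 10112 genes 422 passed, 167 higher and 255 lower, and DESeq2 called 152. With nuclei matched on cluster, library and total UMIs 135 passed, 68 of them shared with the 422, against 407 to 475 in random draws, and 61 of the 422 changed direction. edgeR called 245 without AM368 and 242 without AM372. Axon guidance and adhesion genes were higher in 1 and lower in 8 of 33 (3 and 10 adjusted over the list alone; camera adjusted p = 0.00152, and adjusted p = 0.317 with an estimated correlation). Potassium and HCN channel genes were higher in 1 and lower in 4 of 19 (2 and 7 adjusted over the list alone; camera adjusted p = 0.0380, and adjusted p = 0.317 with an estimated correlation). Gi signalling genes, which act downstream of CHRM2, were higher in 3 and lower in 4 of 21 (3 and 7 adjusted over the list alone; camera adjusted p = 0.0386, and adjusted p = 0.317 with an estimated correlation).

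ACC was compared with LPFC within excitatory neurons to find genes that set the regions apart. With batch as covariate, NKAIN3, which encodes a sodium pump partner, was higher in ACC (152 ± 79.2 against 21.4 ± 5.02 CPM; log2 fold change 2.74 ± 0.19, adjusted p = 0.00196). TIAM1, a Rac activator, was also higher (83.2 ± 12.8 against 34.0 ± 3.4 CPM; log2 fold change 1.29 ± 0.14, adjusted p = 0.0412). These were the 2 genes of 13513 that passed, while 972 had an unadjusted p under 0.05 and DESeq2 called 120. 1 gene passed in batch 1 alone and 0 in batch 2 alone. CHRM1 (-0.14), CHRM2 (-0.013) and CHRM3 (-0.20) did not pass (adjusted p = 0.929, 0.998 and 0.9).

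With the animal as block, 420 genes passed, 261 higher and 159 lower in ACC, 416 of them the same way in 4 of 4 animals. Without AM365 41 passed, and the block gave 302 in batch 1 and 15 in batch 2. FOXF2, a transcription factor gene (22.4 ± 10.5 against 3.49 ± 1.24 CPM; log2 fold change 2.62 ± 0.23, adjusted p = 0.000758), was higher in ACC. The nitric oxide synthase gene NOS1 (log2 fold change 1.80 ± 0.26, adjusted p = 0.00564) and the NMDA receptor subunit gene GRIN3A (116 ± 25.0 against 57.1 ± 13.8 CPM; log2 fold change 1.03 ± 0.091, adjusted p = 0.000758) were also higher there. RORB, a middle-layer transcription factor gene (485 ± 181 against 293 ± 80.4 CPM; log2 fold change -0.70 ± 0.088, adjusted p = 0.00330), and EPHA3, a guidance receptor gene (log2 fold change -0.78 ± 0.085, adjusted p = 0.00170), were higher in LPFC. Beside NKAIN3 (2.72) and FOXF2, the highest fold changes were those of PALMD (2.58), DIAPH3 (2.32), VIT (2.05), TRDN (1.87) and CRISP3 (1.84), and the lowest those of CD53 (-1.80), PTGS1 (-1.74), MKX (-1.68), EYA4 (-1.68), TNC (-1.64) and VAV3 (-1.44). CHRM3 (log2 fold change -0.18 ± 0.10, adjusted p = 0.397) did not pass, nor did CHRM1 (adjusted p = 0.577) or CHRM2 (adjusted p = 0.978). Ionotropic glutamate receptor genes were higher in 4 of 17 and lower in 0 with the block (6 and 0 adjusted over the list alone; camera adjusted p = 0.000527, and adjusted p = 0.608 with an estimated correlation). With batch as covariate 0 passed (4 adjusted over the list alone; camera adjusted p = 0.0343, and adjusted p = 0.921 with an estimated correlation). Middle-layer genes were lower in 2 of 7, RORB and IL1RAPL2 (-0.82) (2 adjusted over the list alone; camera adjusted p = 0.00321, and adjusted p = 0.608 with an estimated correlation). Cadherins CDH9 (0.77), CDH4 (0.74) and CDH13 (0.81) were higher in ACC. Regions shared excitatory subclusters unequally: of E5 nuclei, led by IL1RAPL2 and RORB, 16.5% came from ACC, of E15 14.8%, of E13 21.1% and of E2, with NKAIN3 among its leading genes, 61.3%. With nuclei matched per subcluster within animal, 155 genes passed with the block. NKAIN3 (2.17), FOXF2 (1.99), NOS1 (1.39), GRIN3A (0.73) and EPHA3 (-0.49) still passed, and RORB (-0.30, adjusted p = 0.236) and IL1RAPL2 (-0.26, adjusted p = 0.399) did not.

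In inhibitory neurons edgeR called 0 of 11864 genes between regions with batch as covariate, 352 had an unadjusted p under 0.05 and DESeq2 called 0. Both batches alone gave 0. CHRM1, CHRM2 and CHRM3 had log2 fold changes of 0.088, -0.041 and -0.017, each at an adjusted p of 1. With the animal block 51 genes passed, 28 higher and 23 lower in ACC, all 51 the same way in 4 of 4 animals. DESeq2 called 27, and 20 passed with nuclei matched per cluster. The block gave 1 in batch 1 and 0 in batch 2, and 33, 25, 13 and 11 without AM365, AM367, AM368 and AM372. The neuropeptide gene NPY (18.7 ± 18.1 against 2.61 ± 1.54 CPM; log2 fold change 2.62 ± 0.45, adjusted p = 0.0142) was higher in ACC, as were SST (74.7 ± 30.2 against 43.4 ± 12.7 CPM; log2 fold change 0.79 ± 0.16, adjusted p = 0.0446) and the GABA receptor subunit gene GABRG1 (log2 fold change 1.40 ± 0.23, adjusted p = 0.0113). SEC14L5 (log2 fold change -1.14 ± 0.16, adjusted p = 0.00298), the potassium channel gene KCNA1 (log2 fold change -0.81 ± 0.17, adjusted p = 0.0446) and the myelin gene MBP (-0.63) were lower. Interneuron peptides and calcium-binding proteins were higher in 3 of 13 with the block, NPY, SST and RELN (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.58e-05, and adjusted p = 0.540 with an estimated correlation). With batch as covariate 0 of 12 passed (1 adjusted over the list alone; camera adjusted p = 0.00456, and adjusted p = 0.974 with an estimated correlation). None of the 13 measured mitochondrially encoded genes passed with the block, 9 did adjusted over the list alone, and the median was 0.42 (camera adjusted p = 1.01e-08, and adjusted p = 0.540 with an estimated correlation).

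The region difference itself was tested between excitatory and inhibitory neurons, and 294 of 13461 genes passed, 208 more positive in excitatory neurons. IL1RAPL2, a synaptic adhesion gene (difference of log2 fold changes -1.44 ± 0.092, adjusted p = 7.70e-07), was lower in ACC in excitatory (-0.82) and higher in inhibitory neurons (0.62). CDH13 (difference of log2 fold changes 1.21 ± 0.089, adjusted p = 2.02e-06), NKAIN3 (difference of log2 fold changes 2.32 ± 0.17, adjusted p = 2.02e-06) and GRIN3A (difference of log2 fold changes 0.86 ± 0.092, adjusted p = 0.000105) had larger differences in excitatory neurons. CHRM1, CHRM2 and CHRM3 did not pass (adjusted p = 0.738, 0.955 and 0.610). Nuclei were not matched on subcluster for this term, so unequal subcluster shares stay open for it. As given above, the excitatory IL1RAPL2 difference no longer passed with nuclei matched per subcluster, while those of NKAIN3 and GRIN3A still did.

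**Figure D4:**
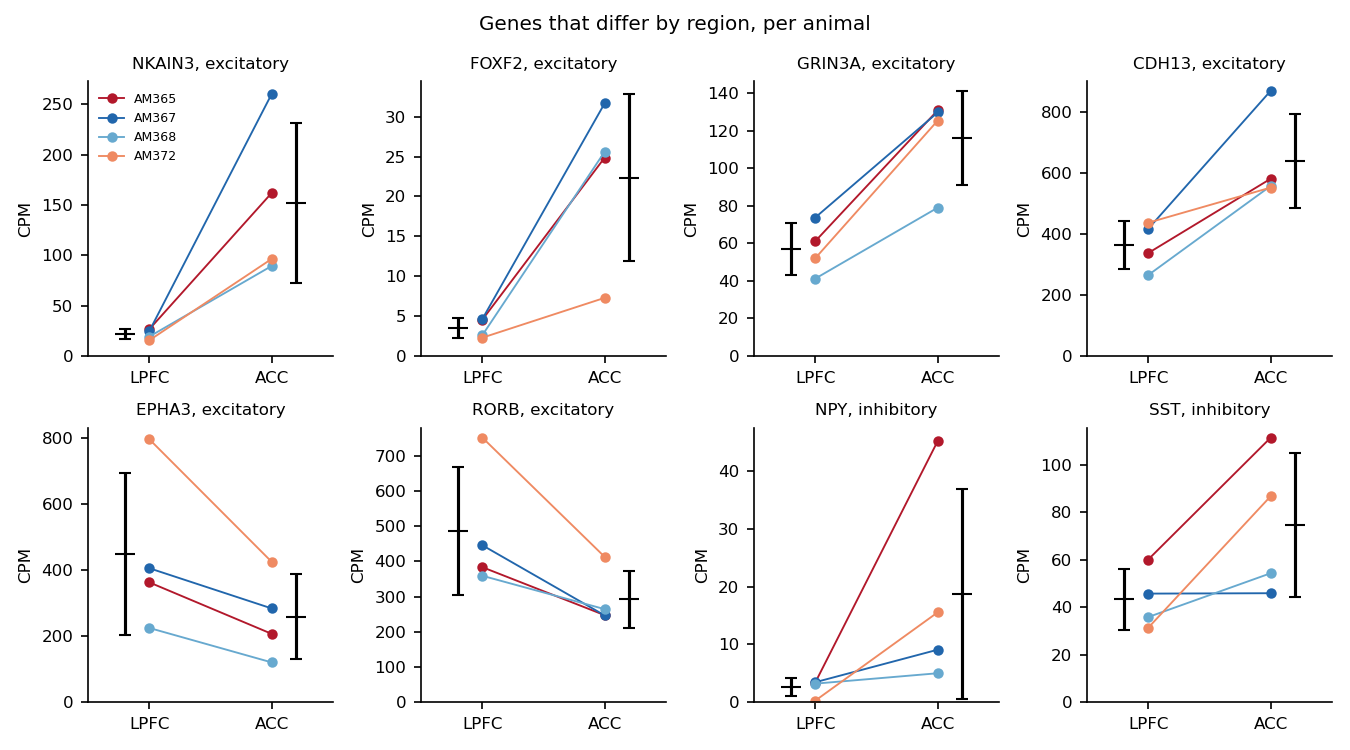
CPM (y axes) in LPFC and ACC for named excitatory and inhibitory genes; joined points are 1 animal and black marks the mean ± SD of 4 animals. NKAIN3 averaged 21.4 CPM in LPFC and 152 CPM in ACC.

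Among glia, astrocytes differed between regions with the animal block. NRP2, a semaphorin receptor gene, was higher in ACC astrocytes (442 ± 247 against 115 ± 108 CPM; log2 fold change 2.08 ± 0.24, adjusted p = 0.000211), as was CD44, an adhesion gene of reactive astrocytes (log2 fold change 0.84 ± 0.15, adjusted p = 0.0171). The calcium channel subunit gene CACNA2D3 (log2 fold change -1.38 ± 0.21, adjusted p = 0.00694) and the guidance receptor gene DCC (log2 fold change -1.13 ± 0.19, adjusted p = 0.00936) were lower. Of 6527 genes 16 passed, 3 higher and 13 lower. DESeq2 called 3, and 4 passed with nuclei matched per cluster within animal, CD44 (0.79, adjusted p = 0.0754) no longer among them. Cluster 24, with CD44 among its leading genes, held 44.9% of ACC and 21.2% of LPFC astrocytes, and cluster 9 held 49.7% and 69.7%. Both clusters follow batch, with 17.7% of cluster 24 and 97.1% of cluster 9 nuclei from batch 1. Batch 2 gave 107 and 102 astrocytes in its ACC libraries and 75 and 77 in its LPFC libraries. Batch 1 gave 239 and 83 in ACC, and 338 and 177 in LPFC. The pooled shares thus mix batch with region. Without AM365 1 passed, and the block gave 19 in batch 1 and 15 in batch 2. Glial activation genes were higher in 1 of 6 (3 adjusted over the list alone; camera adjusted p = 0.00499, and adjusted p = 0.442 with an estimated correlation). In oligodendrocyte precursors the block gave 2 genes of 5506, ENTPD1 higher (log2 fold change 1.40 ± 0.27, adjusted p = 0.0428) and CHST9 lower in ACC (log2 fold change -0.88 ± 0.18, adjusted p = 0.0428), with 10 in batch 1, 0 in batch 2, 0 without AM365, 0 by DESeq2 and 0 matched per cluster. In oligodendrocytes and microglia edgeR with the block called 0 genes, with 704 and 209 at an unadjusted p under 0.05 and 0 by DESeq2 in both. In oligodendrocytes the same fit called 61 genes with nuclei matched per cluster within animal, 18 without AM368 and 14 in batch 1. With batch as covariate edgeR called 0 genes in oligodendrocytes, precursors, astrocytes and microglia, with 143, 169, 236 and 60 at an unadjusted p under 0.05, and DESeq2 called 0, 0, 1 and 0. Each batch alone gave 0. In oligodendrocytes with batch as covariate, potassium and HCN channel genes leaned towards LPFC as a list (0 of 10 passed, 2 adjusted over the list alone; median -0.39; camera adjusted p = 8.02e-05, and adjusted p = 0.477 with an estimated correlation). Mitochondrially encoded genes leaned towards ACC (0 of 9 passed, 1 adjusted over the list alone; camera adjusted p = 0.00535, and adjusted p = 0.477 with an estimated correlation). Cluster 2 held 37.9% of ACC and 34.4% of LPFC oligodendrocytes, cluster 1 held 29.2% and 62.6%, and cluster 19 held 28.0% and 1.00%. These follow single libraries: cluster 19 held 81.6% of oligodendrocytes in the ACC library of AM368 and at most 2.31% in any other, and cluster 2 held 99.8% of those of AM365.

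Age was compared between 2 older and 2 younger animals, so each value rests on a pair of animals per group. With batch also fitted, little spread between animals is left to measure, so the p-values lean on dispersions shared over genes. Differences between single animals cannot be told from age here. In excitatory neurons 762 genes had an unadjusted p under 0.05, where about 741 are expected by chance. In excitatory neurons the semaphorin genes SEMA3E (115 ± 69.3 against 31.6 ± 18.1 CPM; log2 fold change 1.85 ± 0.20, adjusted p = 0.000343) and SEMA3A (log2 fold change 1.30 ± 0.20, adjusted p = 0.0112), whose products guide axons, were higher in the older animals. So was the orexin receptor gene HCRTR2 (2.40), and the transcription factor gene ZNF423 (log2 fold change -1.19 ± 0.22, adjusted p = 0.0373) was lower. SEMA3E, SEMA3A and HCRTR2 are leading genes of excitatory cluster 28, which held 4.56% and 6.83% of excitatory neurons in the older AM365 and AM372, and 1.33% and 6.47% in the younger AM367 and AM368. Nuclei were not matched on cluster for age. CHRM1 to CHRM4 had an adjusted p of 1. Of 14811 genes 27 passed, 12 higher and 15 lower in the older animals. The count was 0 without the batch covariate and 0 in ACC alone, and other settings moved it both ways, as given below. DESeq2 called 11, and edgeR called 0 without AM365, 0 without AM372, 184 without AM367 and 68 without AM368. Deep-layer genes were higher in 2 of 15 (5 adjusted over the list alone; camera adjusted p = 9.33e-07, and adjusted p = 0.954 with an estimated correlation). Axon guidance and adhesion genes were higher in 2 of 37 (2 adjusted over the list alone; camera adjusted p = 1.07e-08, and adjusted p = 0.954 with an estimated correlation). In inhibitory neurons edgeR called 0 of 13190 genes, with 527 at an unadjusted p under 0.05 and 0 by DESeq2, and edgeR called 136 without AM365, 89 without AM367 and 5 without AM368.

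In glial classes a few genes passed between the older and the younger animals. An unadjusted p under 0.05 was no more frequent than by chance. Oligodendrocytes had 399 such genes with 543 expected, precursors 308 with 355 expected, and microglia 294 with 301 expected. In oligodendrocytes the laminin gene LAMA3 was higher in the older animals (291 ± 52.8 against 7.98 ± 1.06 CPM; log2 fold change 5.30 ± 0.41, adjusted p = 5.29e-07) and the transporter gene SLC9C1 lower (log2 fold change -4.33 ± 0.57, adjusted p = 0.000752). Of 10866 genes 11 passed there, 5 higher and 6 lower. DESeq2 called 4, and edgeR called 1, 18, 0 and 6 without AM365, AM367, AM368 and AM372. Cluster 2 held 55.5% of older and 8.01% of younger oligodendrocytes, but the older share is AM365 (99.8%) and not AM372 (1.37%). Cluster 1 held 92.9% of oligodendrocytes of AM372, 79.8% of AM367, 44.1% of AM368 and 0 of AM365. In oligodendrocyte precursors the AMPA receptor gene GRIA4 (log2 fold change 2.91 ± 0.49, adjusted p = 0.0297) and the netrin receptor gene UNC5D (log2 fold change 2.67 ± 0.34, adjusted p = 0.00679) were among 4 higher genes, and TRPM3 (-1.56) was 1 of 2 lower ones. SEMA3D had 42 UMIs in the older and 0 in the younger animals. DESeq2 called 1 gene there, and edgeR called 160, 24, 0 and 113 without AM365, AM367, AM368 and AM372. In microglia 6 genes passed, among them KCNAB1 (log2 fold change 3.02 ± 0.36, adjusted p = 0.00263), SHTN1 (2.28) and RIN3 (3.53) higher and TSHZ2 (-2.70) lower. DESeq2 called 2, and edgeR called 1 without the batch covariate, 0 in ACC alone, and 82, 49, 32 and 77 without AM365, AM367, AM368 and AM372. BICC1 had 126 UMIs in the older and 2 in the younger animals, and COL26A1 68 and 3. Glial activation genes in microglia passed in 0 of 10 (1 adjusted over the list alone; camera adjusted p = 0.00786, and adjusted p = 0.921 with an estimated correlation). In astrocytes edgeR called 0 of 7969 genes, with 278 at an unadjusted p under 0.05 and 1 by DESeq2, and 107, 47, 22 and 44 without AM365, AM367, AM368 and AM372. Astrocyte clusters followed batch and not age: cluster 9 held 62.5% of astrocytes of AM365 and 94.9% of AM367 in batch 1, and cluster 24 held 88.3% of AM368 and 85.1% of AM372 in batch 2.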

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

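Chosen only after their results were seen were the tests of subcluster shares and of depth for the CHRM1-only against CHRM2-only genes, the tests of free RNA and of RNA of other cell types, the test of 1 animal alone in astrocytes and the random draws of equal numbers of nuclei. Among 436 groups of 4 values, 33 held 1 library or animal far from the other 3, with a gap to its neighbour above the critical value of Dixon's test. Chance marks about 1 in 20 groups, and here it was 1.51 in 20. AM372 and AM365, the older animals, and AM367 and AM368, the younger ones, all appear among them, and no explanation was tested for single values.

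AM367 had few oligodendrocytes in LPFC, 14.5% of nuclei against 28.5 to 31.2% in the other 3 animals, and many astrocytes in ACC, 12.5% against 4.49 to 5.34%. AM365 had 0.110% vascular cells in ACC against 0.313 to 0.352%. A CHRM5 UMI was seen after thinning in 0.136% of excitatory neurons in ACC of AM372 and in 0.213% of inhibitory neurons in LPFC of AM365, against 0 in the other animals. Each share is 1 nucleus. In LPFC inhibitory neurons AM372 had 1598 CPM of CHRM3 against 1061 to 1143 CPM in the others.

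Among genes of the receptor class comparisons, CHRM1-only excitatory neurons had PDZRN4 at 1065 CPM in AM372 against 421 to 511 in the other 3 animals and SMYD1 at 1.32 CPM in AM372 against 0. CHRM1-only inhibitory neurons had SMOC1 at 7.66 CPM in AM365 against 32.6 to 35.5, CHRNA2 at 7.66 CPM in AM365 against 16.3 to 17.1 and GRM8 at 689 CPM in AM372 against 288 to 353, and CHRM2-only inhibitory neurons had PPFIBP2 at 44.6 CPM in AM367 against 26.5 to 29.5. In CHRM2-positive excitatory neurons the values were QRFPR at 21.5 CPM in AM367 against 44.1 to 45.7 and PDZRN4 at 2044 CPM in AM372 against 1080.2 to 1223, and in CHRM2-negative ones QRFPR at 7.75 CPM in AM372 against 0.934 to 1.96 and CDH9 at 194 CPM in AM368 against 408 to 436. CHRM2-positive inhibitory neurons had COL21A1 at 2.26 CPM in AM365 against 1.40 to 1.5, and CHRM2-negative ones HTR1F at 148 CPM in AM372 against 51.8 to 64.0 and RGS12 at 288 CPM in AM365 against 433 to 448. Inhibitory neurons of both regions together had ACHE at 8.98 CPM in AM365 against 6.71 to 6.80 and CHRNA7 at 121 CPM in AM372 against 107 to 109.7.

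Among genes named between regions, ACC excitatory neurons had PTGS1 at 10.3 CPM in AM368 against 4.33 to 4.90, EYA4 at 4.72 CPM in AM367 against 14.3 to 16, GRIN3A at 79.1 CPM in AM368 against 126 to 131, RORB at 413 CPM in AM372 against 247 to 265 and CDH13 at 870.2 CPM in AM367 against 552 to 581. LPFC excitatory neurons had PALMD at 8.36 CPM in AM367 against 1.27 to 2.38. In inhibitory neurons ACC had CDH4 at 378 CPM in AM367 against 282 to 294, and LPFC had NPY at 0.299 CPM in AM372 against 3.24 to 3.48 and LRMDA at 56.6 CPM in AM372 against 26.6 to 29.0. LPFC oligodendrocyte precursors had CHST9 at 2676 CPM in AM372 against 783 to 982, and LPFC astrocytes CD44 at 1337 CPM in AM368 against 45.0 to 262 and CACNA2D3 at 1416 CPM in AM372 against 324 to 470.1.

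Effects also differed between groups by their own tests. The CHRM1-only minus CHRM2-only difference in excitatory neurons differed between ACC and LPFC in 47 genes, and the region difference differed between excitatory and inhibitory neurons in 294 genes. Nuclei were not matched on subcluster for either test.

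The first pattern weighed is the genes that differ between CHRM1-only and CHRM2-only neurons. Depth of the nuclei as the whole cause is argued against in excitatory neurons, since 987 genes passed with excitatory nuclei matched on total UMIs, beside 1079 before. In inhibitory neurons 296 passed beside 419, between the bounds set, so depth stays open there. Unequal shares of subclusters are a candidate explanation for most of the difference: with nuclei matched on cluster and library 19 genes passed in excitatory neurons, where 5 random draws of as many nuclei gave 421 to 651, and 14 in inhibitory neurons, where draws gave 62 to 148. A difference within subclusters stays open for the genes that still passed, and which molecules follow receptor expression inside a subcluster was not tested further.

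The second pattern is the genes that differ between regions with the animal as block. One animal alone as the source is argued against by direction only. Of genes called in 3 animals, at least 80.9% moved the same way in the animal left out in excitatory neurons. In inhibitory neurons at least 84% did. The excitatory count nonetheless fell from 420 to 41 without AM365. AM365 itself was held against those 41 genes alone, so how far the size of the other differences rests on it stays open. In astrocytes the lowest percent was 65.2%, so 1 animal alone stays open there. RNA of other cell types stays open too. It can raise a gene only where another class holds at least as much, as was so for 66.9% of the excitatory and 70.6% of the inhibitory genes that passed. Glial marker lists, the planned test, had medians of at most 0.188 and 0.192 in size, but single markers ran to 0.784 in excitatory and to -1.04 in inhibitory nuclei, so these medians decide nothing. Excitatory markers in inhibitory nuclei had a median of -0.443, from -0.601 to 0.102. Unequal shares of subclusters may account for part of the excitatory genes, since 155 passed when nuclei were matched per cluster within animal and 370 to 444 in random draws, and in inhibitory neurons they stay open, as 20 passed, below the median of 37 of the draws but within their 14 to 55. A biological difference between ACC and LPFC stays open and was not tested apart from these.

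The third pattern is the even spread of CHRM1 over subclusters beside the uneven spread of CHRM2. Few CHRM1 UMIs as the cause are argued against: CHRM2 UMIs thinned to the number of CHRM1 UMIs had a coefficient of variation at or below that of CHRM1 in 0 of 100 draws in excitatory neurons and 0 of 100 in inhibitory neurons. Free RNA in droplets is argued against by the ratio of CHRM1 CPM in neurons to glia, which was at least 5.45 in each of the 4 animals. With UMIs pooled over animals, the coefficient of variation of CHRM1 was 0.259 in excitatory and 0.401 in inhibitory neurons. Even expression at this number of UMIs would give 0.104 to 0.322 and 0.161 to 0.644, so CHRM1 lies within both ranges. The design gives no group for a biological explanation of this pattern, so none was tested, and how well the annotation covers the end of the CHRM1 transcript was not tested.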

How the results depend on the processing

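Added after the data were seen were every alternative of the region fits with the animal block, those of the CHRM1-positive against CHRM1-negative comparison, and the random draws of nuclei. The other alternatives were planned. Over 285 named genes and 4325 gene and alternative pairs, 3487 kept direction and side of the threshold, 825 kept direction and no longer passed, 2 passed only under the alternative and 11 reversed. Counts outside 1.5 times the reported one follow. The cause was not tested, except where fewer nuclei, animals or genes enter by construction.

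The region count in excitatory neurons (2 with batch as covariate) was 420 with the animal block, 1 without the batch covariate, 120 by DESeq2, 64 without the low-count filter, 1 in batch 1, 0 in batch 2 and 1 with nuclei matched per cluster. Leaving out single libraries gave 1 to 10, the 10 without the ACC library of AM368 and 4 without the LPFC library of AM368. With the animal block the count of 0 became 51 in inhibitory neurons, 2 in oligodendrocyte precursors and 16 in astrocytes. Without the low-count filter it became 26 in inhibitory neurons, 2 in oligodendrocytes, 2 in precursors, 31 in astrocytes and 2 in microglia. In astrocytes DESeq2 called 1, and leaving out libraries gave 0 to 2, the 2 without the ACC library of AM368. Leaving out 1 library gave 0 to 0 in inhibitory neurons, oligodendrocytes, precursors and microglia.

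With the animal block the excitatory count of 420 became 1005 without the low-count filter, 15 in batch 2 and 155 with nuclei matched per cluster, and 41 to 426 with 1 animal left out, the 41 without AM365. Inhibitory neurons went from 51 to 27 by DESeq2, 214 without the filter, 1 in batch 1, 0 in batch 2, 20 with nuclei matched per cluster, and 14 and 31 in random draws 1 and 4. Leaving out an animal gave 11 to 33, with 33 without AM365, 25 without AM367, 13 without AM368 and 11 without AM372. Oligodendrocytes went from 0 to 39 without the filter, 14 in batch 1, 61 matched per cluster, and 0 to 18 with 1 animal left out, 18 without AM368 and 3 without AM372. For precursors the 2 genes became 0 by DESeq2, 0 with RLE size factors, 4 without the filter, 10 in batch 1, 0 in batch 2, 0 at 1000 UMIs per nucleus, 0 with doublets kept and 0 matched per cluster, and 0 to 3 with 1 animal left out, 0 without AM365. Astrocytes went from 16 to 3 by DESeq2, 45 without the filter, 4 matched per cluster and 1 to 23 with 1 animal left out, 1 without AM365. Microglia went from 0 to 3 without the filter, 2 in batch 1 and 2 in batch 2, and stayed at 0 with each animal left out. Without subcluster E6, of low depth, the excitatory counts were 2 with batch as covariate and 417 with the block.

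Without the replicate block, which pairs the sums of 1 animal, CHRM1-only against CHRM2-only gave 110 genes in excitatory and 49 in inhibitory neurons, and CHRM2-positive against CHRM2-negative gave 87 and 36. DESeq2 called 499, 167, 594 and 152. ACC nuclei alone gave 585, 136, 790 and 107, and LPFC nuclei alone 700, 164, 798 and 238. Matched on cluster the counts were 19, 14, 25 and 135. Random draws of as many nuclei as that match gave 434, 421, 566, 506 and 651 in CHRM1-only against CHRM2-only excitatory neurons and 148, 62, 135, 137 and 86 in inhibitory neurons. For CHRM2-positive against CHRM2-negative such draws gave 898 to 1015 and 407 to 475. CHRM2-positive against CHRM2-negative inhibitory neurons gave 789 when not matched on total UMIs. Leaving out an animal gave 728 to 952 and 222 to 340 in the first comparison (inhibitory 222 without AM368 and 273 without AM372), and 752 to 1158 and 242 to 462 in the second (excitatory 752 without AM372; inhibitory 245 without AM368 and 242 without AM372). Of 14 cholinergic genes, 6 differed between excitatory and inhibitory neurons, 3 by DESeq2, 3 in LPFC alone, and 4 to 5 with 1 animal left out.

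Age counts rest on 2 animals per group. Without the batch covariate they were 0 in excitatory neurons, 3 in oligodendrocytes, 0 in precursors and 1 in microglia. DESeq2 called 11, 4, 1 and 2 there and 1 in astrocytes, and RLE size factors gave 3, 4, 0 and 2. Without the low-count filter the counts were 159 in excitatory neurons, 83 in inhibitory neurons, 53 in oligodendrocytes, 31 in precursors, 45 in astrocytes and 37 in microglia. ACC alone gave 0, 25, 1, 13, 1 and 0 in that order, and LPFC alone 3, 88, 1, 3, 13 and 2. At 1000 UMIs per nucleus they were 64, 8, 3, 0, 10 and 23, and with doublets kept 2 in excitatory neurons, 20 in oligodendrocytes, 0 in precursors and 1 in astrocytes. Leaving out an animal, in fits without batch on 3 animals where the lone animal of a group is assumed to vary like the others, gave 0 to 184, 0 to 136, 0 to 18, 0 to 160, 22 to 107 and 32 to 82. The excitatory count was 0 without AM365 or AM372, 184 without AM367 and 68 without AM368. The inhibitory count was 136 without AM365, 89 without AM367 and 5 without AM368. Oligodendrocytes gave 1, 18, 0 and 6 without AM365, AM367, AM368 and AM372, precursors 160, 24, 0 and 113, astrocytes 107, 47, 22 and 44, and microglia 82, 49, 32 and 77.

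No class share and no receptor share passed under any alternative, with 0 to 0 when 1 library was left out, but a single share could hardly pass these tests after adjustment, so this does not show stability. Of 337 pairs of gene list and comparison 54 passed with the preset correlation, 0 with an estimated correlation, 35 by fry and 74 with the animal block in the region comparisons. The odds ratio of CHRM1 with CHRM2 in excitatory neurons was 1.35 with cluster in the strata and 0.963 to 1.13 with 1 animal left out. For CHRM1 with CHRM3 in excitatory neurons it was 3.21 with strata of library alone and 1.70 to 2.05 with 1 animal left out. CHRM2 with CHRM3 in excitatory neurons gave 0.729 with cluster, 0.304 with library alone and 0.107 to 0.151 with 1 animal left out. In inhibitory neurons CHRM2 with CHRM3 gave 2.23 with cluster, 0.954 in ACC, 2.13 in LPFC and 1.27 to 1.49 with 1 animal left out. CHRM1 with CHRM2 gave 0.814 to 1.11 and CHRM1 with CHRM3 0.668 to 0.849. The odds ratio of CHRM1 with CHRM3 in ACC excitatory neurons could not be computed for every animal.

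Named genes reversed as follows on the log2 scale. In CHRM1-only against CHRM2-only neurons matched on cluster and library, GRIK1 became 0.063 and KCNT2 0.0022 in excitatory neurons, and HTR1F -0.097, CLSTN2 -0.31, SV2C -0.12 and UNC5C -0.29 in inhibitory neurons. In CHRM2-positive inhibitory neurons matched on cluster EPHA3 became 0.19 and CACNB2 0.11. With age, SLC16A9 became -0.22 in LPFC excitatory neurons. In CHRM1-positive against CHRM1-negative excitatory neurons from ACC alone, ERBB4 became -0.042 and PLD5 0.031. Depth limits the rarest receptors: 4 CHRM5 UMIs in excitatory neurons and 1 in inhibitory neurons allow no comparison.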

Other observations

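The comparison of CHRM1-positive with CHRM1-negative neurons and the counts over other splits of the samples were chosen only after the results were seen. Counts of the real splits and those within batches repeat results given above. CHRM1-positive nuclei were set against CHRM1-negative nuclei matched on total UMIs within library, to see whether CHRM1 marks a distinct set of neurons as CHRM2 does. In excitatory neurons 12 of 12019 genes passed in edgeR, 3 higher and 9 lower in CHRM1-positive neurons, 590 had an unadjusted p under 0.05, and DESeq2 called 0. HTR2C was lower (23.8 against 49.2 CPM; log2 fold change -1.07 ± 0.16, adjusted p = 0.00311), as was RGS12 (log2 fold change -0.47 ± 0.086, adjusted p = 0.0204), and HTR1F was higher (log2 fold change 0.36 ± 0.069, adjusted p = 0.0325). CHRM3 did not pass (log2 fold change 0.06 ± 0.042, adjusted p = 0.983). In inhibitory neurons 4 of 8831 genes passed, all lower: CDH8 (log2 fold change -0.62 ± 0.10, adjusted p = 0.0224), PAWR (-1.41), MAN1A1 (-0.87) and PDE1A (-0.79). 492 had an unadjusted p under 0.05 and DESeq2 called 0. With 1 animal left out the counts were 0 to 6 in excitatory and 0 to 16 in inhibitory neurons.

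Other splits of the 8 libraries or sums were counted for each comparison across genes. Of 35 splits into 4 and 4, the 8 that part both libraries of every animal are too few for a share under 0.05. Between regions with batch as covariate, the real split called 2 genes in excitatory neurons and the highest of the other 7 called 0, so 1 of 8 splits was as large. In inhibitory neurons, oligodendrocytes, precursors, astrocytes and microglia the real split called 0 and the highest other called 0, so 8 of 8 were as large. Splits that parted fewer pairs called up to 45 genes in excitatory neurons, 143 in inhibitory neurons and 328 in oligodendrocytes. In precursors, astrocytes and microglia they called up to 21, 81 and 49. Apart from the astrocyte 81, these came from splits that part no pair, which points to differences between animals as a structure of the samples. The 81 came from a split that parts AM365 and AM372 by region, so it mixes region with animal. Splits that part no pair called 5, 2 and 20 in astrocytes. The excitatory 45 is the split that follows the batches, and the others that part no pair called 15 and 32. That batch split called 45, 42, 11, 3, 2 and 7, in the order of classes above, when fitted alone. Within batches the region counts were 1 and 0 in excitatory neurons and 0 and 0 in the others.

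With the animal block the real split called 420 genes in excitatory neurons and the highest other of the 8 called 0, 51 and 0 in inhibitory neurons, 0 and 2 in oligodendrocytes, 2 and 1 in precursors, 16 and 0 in astrocytes, and 0 and 3 in microglia. Splits with fewer pairs parted reached 641, 416, 411, 32, 107 and 26, and 24 of 27 of them could be fitted. With the block such splits compare only the animals whose pair they part. In every class but microglia the highest came from ACC against LPFC in the older AM365 and AM372 alone. Those counts are thus region comparisons in part of the animals. ACC against LPFC in the younger AM367 and AM368 alone called 0 genes in every class. In such fits the region difference of the animals whose pair is not parted adds to the spread, so this 0 does not show its absence. For CHRM1-only against CHRM2-only the real split called 1079 and the highest other of the 8 called 0 in excitatory neurons, and 419 and 3 in inhibitory neurons. For CHRM2-positive against CHRM2-negative these were 1295 and 0, and 422 and 1. Splits with fewer pairs parted reached 0 and 129 in the first comparison and 1 and 216 in the second. The 129 and the 216 came from the class contrast in AM368 and AM372 alone. For excitatory against inhibitory neurons the real split called 6 cholinergic genes and the highest other 0.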
